A study of Mus musculus with 32 samples.

How the data were processed

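Hippocampal total RNA of mice was labelled with biotin and hybridised to Illumina bead arrays, 1 array per sample, per the labels. The authors deposited a table of probe intensity for 32 arrays and 25697 probes, which per the file headers holds the mean signal of each probe on a linear scale with no normalization between arrays. The lowest intensity was 27.04, so no background had been subtracted. A detection p-value stands beside each signal in the deposited table, per the file headers, and its values were multiples of 1 part in 798. The submitters' processing notes name GenomeStudio, and its version is not given in the sources used here. A second deposited table holds normalized intensity values whose method is not given in the sources used here. Within each array these values rose in the order of the signals, the arrays had nearly the same distribution, with medians from 19.67 to 19.78, and 24.4% of the values were below 0. They served only as an alternative, with values under 16 set to 16 before taking log2.

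The signals were processed in R 4.3.3 with limma 3.58.1. The neqc function corrected background by normexp with negative controls inferred from the detection p-values, added an offset of 16, quantile-normalized the arrays and took log2. A probe was kept if its detection p-value lay under 0.05 on at least 3 arrays, which 14745 probes met. Of all probes, 23978 carried 1 gene symbol, 1719 carried none and 0 carried several. A match by gene number to the mouse gene table of the GRCm38.p6 assembly found 23962 of them and changed 0 symbols. For each gene the probe with the highest mean over all arrays was tested, a choice that mattered for 2608 genes with more than 1 probe. This left 11178 features, 10308 named genes and 870 probes without a symbol.

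Groups came from the titles and genotype labels. One limma fit of 7 group means over all 32 arrays gave 10 comparisons, with 25 residual and 4.087 prior degrees of freedom. These were the age effect (old minus young) in wild type, ASC knockout and CIAS knockout, the difference of each knockout's age effect from that of wild type, and each knockout against wild type of the same age. The CASP11 knockout was given only at the young age. Tests were 2-sided with Benjamini-Hochberg adjustment over all features of a comparison, and a gene was called at adjusted p under 0.05. The labels do not say whether the samples of a group came from separate animals. The p-values thus measure only the spread between these samples, which may be technical. Sex-linked transcripts differed between arrays of both wild type groups and of the young ASC and CASP11 knockouts. Those groups therefore held RNA of more than a single animal, though not every sample need be a separate animal. The number of arrays sets the precision.

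The choices in this paragraph were made before the data were examined. Genes named in the text were the targeted genes and Casp1, the 12 with the largest fold in each direction for age in wild type and the 10 for every other comparison, and of each gene list up to 4 members with the smallest adjusted p. The 37 gene lists covered immune pathways, cell types, brain regions, signalling and stress responses, and 35 of them had at least 5 measured members. Each list was tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were alternatives. An age score per array was the mean log2 signal over the genes called for the mean age effect of the 3 genotypes, with falling genes entered with a minus sign. It rested on 687 genes, 382 of them rising. The difference in old-minus-young score between a knockout and wild type was tested by an exact permutation of genotype within age over 32340 splits, 2-sided.

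Among the genes this rule names, the examples given in the text were picked after their leave-one-out results had been seen. A gene given without a further remark kept its call when any single array of the 32 was left out. Of 292 called results of named genes, 141 did so, and 126 kept the call under all the other alternatives planned beforehand, so the examples are steadier than the named genes as a whole. The counts of genes called and the age score were recomputed with quantile normalization without background correction, an offset of 50, the deposited normalized values, no filter and a strict filter on dim probes (detection p under 0.01 on every array of at least 1 group), and with a covariate for sex-linked transcripts and the replicate number as a block. Each array was left out in turn, for the score each array of the genotypes compared. The counts alone were recomputed with array weights, trended and robust variance, fits of only the groups compared, all probes tested separately and a threshold of at least 1.5-fold, and the score alone over rising genes, falling genes or the 200 with the smallest p. The gene list tests were rerun with quantile normalization, the deposited values and the block. Further alternatives were added after the data had been seen. These were fits without wild type old replicate 6, alone or with covariates for sex-linked transcripts, choroid plexus markers or 3 components of the variation within groups, list tests without that array, and a permutation of the age score in which its genes were chosen anew for each relabeling.

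The procedure was tested on simulated data built on these arrays, with 100 genes changed at each of 2 sizes among 11178. For age in wild type, 84% of the genes changed by 1.5-fold and 97% of those changed by 2-fold were recovered, with 9 unchanged genes called. For the difference in age effect of the CIAS knockout the shares were 65% and 92%, with 4 unchanged genes called. For the young CASP11 knockout they were 86% and 96%, with 6 unchanged genes called. In 100 simulations with no genotype difference in 400 age-responsive genes, the exact permutation p of the age score lay under 0.05 in 11 for ASC and in 6 for CIAS. With the genes chosen anew, 1 of 20 simulations of the ASC comparison lay at or under 0.05. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.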

Results

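Gene expression was profiled in the hippocampus, a brain region needed for forming memories, of young mice aged 1 month and old mice aged 21 to 23 months. The question was how ageing changes the tissue when parts of the inflammasome, a protein complex that activates interleukin-1 family cytokines, are missing. Ageing and age effect here mean old against young. With no age in between, changes soon after 1 month cannot be told apart from changes in later life. Wild type mice gave 4 young and 6 old arrays. The ASC knockout, which lacks the inflammasome adaptor encoded by Pycard, gave 3 young and 6 old arrays, and the CIAS knockout, which lacks the sensor encoded by Nlrp3, gave 3 young and 6 old arrays. The CASP11 knockout, which lacks the caspase encoded by Casp4, gave 4 young arrays. The labels of the old ASC knockout disagree on age, with 23 months in all titles and 21 months in the characteristics of 5 samples. Each array detected between 13172 and 13900 probes, with a median signal between 56.24 and 79.02.

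Within groups the arrays correlated at 0.9855 or more across genes, which are not independent replicates, except in old wild type, where the lowest r was 0.9652 and rose to 0.9894 without replicate 6. In that array the striatal genes Rgs9, Drd1, Tac1 and Drd2, which encode signalling proteins and a neuropeptide of striatal neurons, stood 5.01, 4.51, 4.44 and 4.31 log2 units above the mean of the other 5 old wild type arrays. The dentate gyrus gene C1ql2 stood at -5.08 and the CA1 gene Fibcd1 at -2.96 relative to the same mean. These genes were chosen after their values were seen. The array was kept in the tests planned beforehand, and the counts of called and shared genes are also given for the 31 other arrays. The Y-linked gene Eif2s3y was low on 7 arrays (2 of 4 wild type young, 1 of 6 wild type old, 2 of 3 ASC knockout young, 2 of 4 CASP11 knockout young). In contrast, 0 of 6 old ASC, 0 of 3 young CIAS and 0 of 6 old CIAS knockout arrays showed this. The old wild type array with low Eif2s3y was replicate 4, which also had high Xist, at 8.03. It was the highest of its group for the NF-kB and cytokine, interferon-stimulated, complement, homeostatic microglia, activated microglia and reactive astrocyte lists, though not for MHC genes. Sex was therefore not balanced between old wild type and old knockouts. It was also not balanced between young and old arrays of wild type and, most of all, of the ASC knockout. Nor was it between young CIAS knockout and young wild type. The age effects, their differences and the comparisons with wild type can therefore hold effects of sex.

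The targeted genes lay at or near background. Both probes of Nlrp3 and the probe of Pycard were detected on 0 of 32 arrays. The Nlrp3 probe with the higher mean stood at 4.40 ± 0.050 (SD, n = 4) in young and 4.43 ± 0.049 (SD, n = 6) in old wild type. Its levels were 4.45 ± 0.082 (SD, n = 3) in young and 4.42 ± 0.035 (SD, n = 6) in old ASC knockout. They were 4.42 ± 0.023 (SD, n = 3) in young and 4.42 ± 0.054 (SD, n = 6) in old CIAS knockout, and 4.46 ± 0.027 (SD, n = 4) in CASP11 knockout. Pycard stood at 4.67 ± 0.076 (SD, n = 4) in young and 4.55 ± 0.046 (SD, n = 6) in old wild type. Its levels were 4.62 ± 0.046 (SD, n = 3) in young and 4.64 ± 0.068 (SD, n = 6) in old ASC knockout. They were 4.63 ± 0.070 (SD, n = 3) in young and 4.67 ± 0.098 (SD, n = 6) in old CIAS knockout, and 4.66 ± 0.071 (SD, n = 4) in CASP11 knockout. Of 3 Casp4 probes, 2 were detected on 0 arrays and 1 on all 32. The detected probe stood at 5.45 ± 0.17 (SD, n = 4) in young and 5.32 ± 0.16 (SD, n = 6) in old wild type. Its levels were 5.40 ± 0.093 (SD, n = 3) in young and 5.45 ± 0.074 (SD, n = 6) in old ASC knockout. They were 5.49 ± 0.18 (SD, n = 3) in young and 5.35 ± 0.11 (SD, n = 6) in old CIAS knockout, and 5.45 ± 0.092 (SD, n = 4) in CASP11 knockout. The position of these probes relative to the deleted parts is not given in the sources used here, so none of them checks the genotype labels.

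Casp1, the caspase activated by the inflammasome, was detected on all 32 arrays, at 7.30 ± 0.27 (SD, n = 4) in young and 8.02 ± 0.70 (SD, n = 6) in old wild type (adjusted p = 0.062). Without wild type old replicate 6 it rose by 1.01 in wild type (adjusted p = 9.25e-05), and it was also called with array weights (adjusted p = 0.000613). It stood at 7.60 ± 0.20 (SD, n = 3) in young and 8.17 ± 0.32 (SD, n = 6) in old ASC knockout (adjusted p = 0.57), and at 7.45 ± 0.14 (SD, n = 4) in CASP11 knockout. In the CIAS knockout it rose from 7.29 ± 0.26 (SD, n = 3) to 8.34 ± 0.21 (SD, n = 6), with adjusted p = 0.0445. That call was lost in 20 of the 32 cases with 1 array left out. These were CIAS knockout young replicates 1, 2 and 4 (adjusted p = 0.118, 0.0797 and 0.333), CIAS knockout old replicates 2 to 6 (adjusted p = 0.0561, 0.0839, 0.091, 0.0622 and 0.0745) and 12 arrays of other groups (adjusted p from 0.0505 to 0.0549).

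In ageing wild type mice 4 of 12 complement genes, 9 of 18 homeostatic microglia markers and 4 of 14 MHC class I and II genes rose. The calls for the complement and MHC lists were lost with an estimated correlation (adjusted p = 0.0729 and 0.097). C4b, a component of the classical complement pathway, rose 4.58-fold (log2 2.20, SE 0.17, adjusted p = 6.65e-10), from 7.38 ± 0.42 (SD, n = 4) to 9.57 ± 0.37 (SD, n = 6). All 6 old arrays lay above the young mean. The lysozyme gene Lyz1 rose by 1.46 (SE 0.23, adjusted p = 0.000206). Lyz2, another lysozyme gene, rose by 1.02, but its call was lost in 6 cases with 1 array left out. C1qa and C1qc, subunits of the complement initiator C1q, rose by 0.69 (SE 0.088) and 0.67 (SE 0.12). Trem2, a lipid receptor of microglia, rose from 7.06 ± 0.098 (SD, n = 4) to 7.71 ± 0.24 (SD, n = 6; adjusted p = 9.57e-05), Aif1 by 0.48 (SE 0.085) and Ifit3, an interferon-induced antiviral gene, by 0.91 (SE 0.16). Il33, an alarmin of oligodendrocytes and astrocytes, rose by 0.98 (SE 0.14, adjusted p = 5.92e-05). Of the inflammasome and interleukin-1 genes, 12 were measured and 1 rose, Il33 (2 rose adjusted over the list alone, median log2 0.042, camera adjusted p = 0.142). There were 2, with Casp1 (log2 1.01, adjusted p = 9.25e-05), without wild type old replicate 6.

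Of 18 measured homeostatic microglia markers, 9 rose over all genes and 11 adjusted over the list alone, with 0 falling (median log2 0.33, camera adjusted p = 1.35e-11). This call held at adjusted p = 0.0286 with an estimated correlation. Of the MHC genes 7 rose adjusted over the list alone, with H2-M3 at 0.49 (SE 0.10, median of the list 0.39, camera adjusted p = 5.18e-07). Of 20 interferon-stimulated genes, 2 rose, 8 adjusted over the list alone (median 0.27, camera adjusted p = 2e-05, adjusted p = 0.227 with an estimated correlation). The complement list had 4 members rising adjusted over the list alone (camera adjusted p = 0.000264). Activated microglia genes rose for 4 of 20 members and 7 adjusted over the list alone (camera adjusted p = 0.000494, adjusted p = 0.112 with an estimated correlation). Reactive astrocyte genes rose for 6 of 17 members and 7 adjusted over the list alone, among them S100a6 at 0.57 (SE 0.11) and the cytokine receptor gene Osmr at 0.53 (SE 0.105), with camera adjusted p = 4.91e-05 and adjusted p = 0.146 with an estimated correlation. NF-kB and cytokine genes rose for 2 of 11 members, one of them the pattern recognition receptor gene Tlr2 at 0.54 (SE 0.12), and for 4 adjusted over the list alone (camera adjusted p = 0.0105, adjusted p = 0.227 with an estimated correlation).

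With age in wild type 5 of 20 neurogenesis and immature neuron markers and 3 of 15 proliferation genes fell, and the calls for both lists were lost with an estimated correlation (adjusted p = 0.0729 and 0.0694). The newly formed oligodendrocyte receptor gene Gpr17 fell by 1.497 on the log2 scale (SE 0.10, adjusted p = 5.35e-11), from 9.63 ± 0.048 (SD, n = 4) to 8.13 ± 0.27 (SD, n = 6). The tubulin gene Tubb2a fell by 0.82 (SE 0.15), Dpysl5, an axon guidance gene of immature neurons, by 0.68 (SE 0.10). The mitotic spindle gene Prc1 fell by 0.73 (SE 0.098), the centromere gene Cenpa by 0.65 (SE 0.094) and the matrix glycoprotein gene Tnc by 0.86 (SE 0.13). Adjusted over the list alone, 6 neurogenesis markers fell (median log2 -0.17, camera adjusted p = 0.00154) and 3 proliferation genes (camera adjusted p = 0.0105). Oligodendrocyte precursor and newly formed oligodendrocyte markers were not called as a list in wild type (13 measured, 1 lower, 2 higher and 4 lower adjusted over the list alone, median -0.11, camera adjusted p = 0.145, fry adjusted p = 0.00448). Among 20 myelin and mature oligodendrocyte markers 6 rose, and 8 rose and 1 fell adjusted over the list alone, with the oligodendrocyte gene Hapln2 at 1.16 (SE 0.17). The camera adjusted p of that list was 0.00252, with adjusted p = 0.551 with an estimated correlation and 0.103 without wild type old replicate 6. Extracellular matrix genes had 1 member rising and 3 falling of 21, with 1 and 4 adjusted over the list alone (camera adjusted p = 0.0235, adjusted p = 0.221 with an estimated correlation, 0.128 without that array).

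In all, 633 of 11178 genes were called for age in wild type, 322 higher and 311 lower in old mice. Of 74 named genes among them, 69 had every old array beyond the young mean. Other large changes were those of the uroplakin gene Upk1b at 1.23 (SE 0.16), the lipid transporter gene Abca8a at 1.18 (SE 0.12), the glutathione transferase gene Gstt3 at 1.01 (SE 0.13) and the imprinted gene Mkrn3 at -0.88 (SE 0.15). The cold-inducible gene Rbm3 stood at 1.099 (SE 0.13) by the probe tested, while its 2 other probes gave -0.13 and -0.05. The striatum and thalamus list (16 measured, 1 higher, 1 adjusted over the list alone) and the hippocampal subfield list (16 measured, 1 higher and 1 lower, 1 and 2 adjusted over the list alone) had camera adjusted p = 0.0305 and 0.0347. With an estimated correlation they had adjusted p = 0.133 and adjusted p = 0.605. Without wild type old replicate 6 these were 0.306 and 0.734. The count was 809 without wild type old replicate 6, of which 545 were among the 633, and 380, 411 and 378 without wild type young replicates 2, 3 and 4. A fit of these 2 groups alone called 204 genes and array weights 1044.

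**Figure D1:**
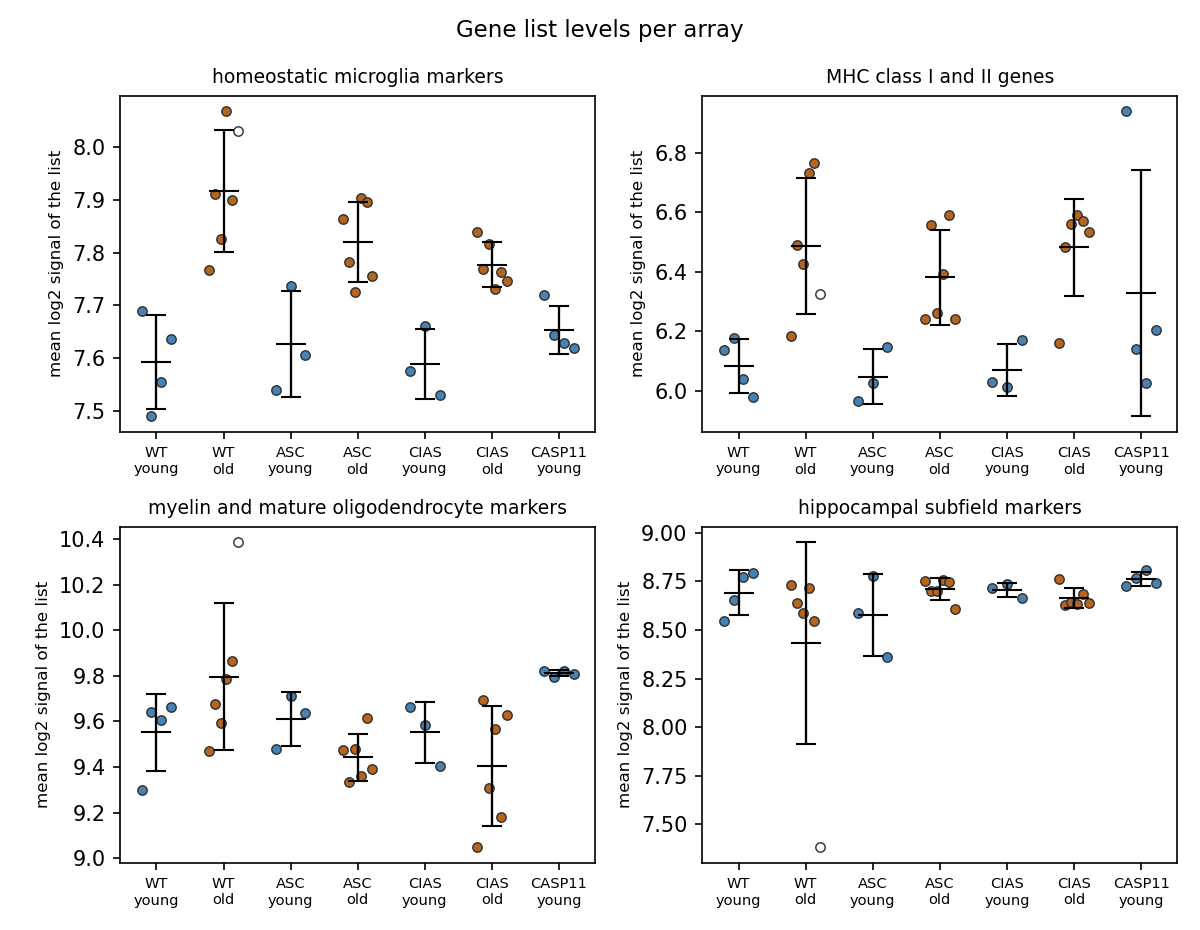
Mean log2 signal per array (vertical axes) of 4 gene lists in the 7 groups, with young arrays in blue, old arrays in brown and bars for mean ± SD. Wild type old replicate 6 is the open circle, lowest for hippocampal subfield markers and highest for myelin markers.

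Ageing in the ASC knockout raised C4b by 1.71 (SE 0.185, adjusted p = 4.17e-06), from 7.32 ± 0.20 (SD, n = 3) to 9.02 ± 0.19 (SD, n = 6). Upk1b rose by 1.53 (SE 0.17), Gstt3 by 1.11 (SE 0.145), Abca8a by 0.90 (SE 0.13) and Tnfsf13b, a cytokine of B cell survival, by 0.69 (SE 0.11). Gpr17 fell by 0.99 (SE 0.11, adjusted p = 4.17e-06), Mkrn3 by 0.97 (SE 0.16), Prc1 by 0.76 (SE 0.11) and the Polycomb gene Cbx8 by 0.73 (SE 0.086). Il33 was 0.65 higher in old mice (SE 0.15) and did not pass the test (adjusted p = 0.058). It passed without wild type old replicate 6 (adjusted p = 0.00758), without CIAS knockout old replicates 2, 5 and 6 (0.0483, 0.0341 and 0.0289), with array weights (0.00153) and in a fit of these 2 groups alone (0.0216). Every old array lay beyond the young mean for all 21 named genes that were called.

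Oligodendrocyte precursor and newly formed oligodendrocyte markers fell as a list in the ASC knockout (13 measured, 1 lower, 2 adjusted over the list alone, median -0.16, camera adjusted p = 1.44e-06, adjusted p = 0.0051 with an estimated correlation). Neurogenesis and immature neuron markers also fell (20 measured, 1 lower, 3 adjusted over the list alone, camera adjusted p = 9.44e-05, adjusted p = 0.0275 with an estimated correlation). The inflammasome and interleukin-1 genes were shifted upward with 0 of 12 called, 2 adjusted over the list alone (median 0.086, camera adjusted p = 0.00859, adjusted p = 0.0442 with an estimated correlation). The following lists were shifted upward with 0 members called over all genes. Homeostatic microglia markers had 6 higher and 1 lower adjusted over the list alone (camera adjusted p = 9.08e-07, adjusted p = 0.0647 with an estimated correlation). MHC genes had 5 higher adjusted over the list alone (camera adjusted p = 1.85e-06, adjusted p = 0.119 with an estimated correlation), and reactive astrocyte genes 4 (camera adjusted p = 9.44e-05, adjusted p = 0.148 with an estimated correlation). Myelin and mature oligodendrocyte markers were shifted downward, with 2 higher and 6 lower adjusted over the list alone and 0 over all genes (median -0.23, camera adjusted p = 0.0058, adjusted p = 0.558 with an estimated correlation). Complement genes (1 of 12 higher over all genes and adjusted over the list alone), activated microglia genes (0 of 20 by both counts) and interferon-stimulated genes (0 of 20 by both) were shifted upward at camera adjusted p of 0.00468, 0.00859 and 0.0238. With an estimated correlation these had adjusted p = 0.123, 0.172 and 0.558.

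Ribosomal protein and oxidative phosphorylation genes were shifted upward and cortical layer, extracellular matrix and proliferation genes downward in old ASC knockout mice, with camera adjusted p of 0.00859, 0.0125, 0.0238, 0.0195 and 0.0475. With an estimated correlation these had adjusted p = 0.148, 0.123, 0.164, 0.164 and 0.119. Of these 5 lists, only the extracellular matrix list had called members, 1 lower over all genes and 2 adjusted over the list alone. The comparison called 31 genes, 11 higher and 20 lower. Without wild type old replicate 6, which enters through the shared spread, the filter and the joint normalization, it called 77, among them all 31. It called 20 with a covariate for sex-linked transcripts and 109 with array weights.

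Ageing in the CIAS knockout raised Upk1b by 1.66 (SE 0.17, adjusted p = 1.01e-06), and C4b by 1.44 (SE 0.185), from 7.63 ± 0.24 (SD, n = 3) to 9.07 ± 0.22 (SD, n = 6). Gstt3 rose by 1.09 (SE 0.145) and Abca8a by 0.95 (SE 0.13). Gpr17 fell by 1.25 (SE 0.11, adjusted p = 4.89e-08), Mkrn3 by 0.97 (SE 0.16) and Prc1 by 0.92 (SE 0.11). The lysosomal protease gene Ctss rose by 0.78 (SE 0.15, adjusted p = 0.00645), with adjusted p = 0.15 without CIAS knockout young replicate 4. Trim30a, an interferon-induced gene, rose by 0.715 (SE 0.134, adjusted p = 0.00586), with adjusted p = 0.0916 without that array. All 28 named genes called had every old array beyond the young mean.

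In the CIAS knockout, oligodendrocyte precursor and newly formed oligodendrocyte markers fell as a list (13 measured, 1 lower, 3 adjusted over the list alone, camera adjusted p = 2.03e-05, adjusted p = 0.015 with an estimated correlation). MHC genes were shifted upward (1 of 14 higher, 2 adjusted over the list alone, median 0.35, camera adjusted p = 1.3e-06, adjusted p = 0.169 with an estimated correlation). So were homeostatic microglia markers (1 of 18 higher, 7 adjusted over the list alone, camera adjusted p = 8.86e-05, adjusted p = 0.202 with an estimated correlation). Reactive astrocyte genes had 2 of 17 higher and 5 adjusted over the list alone (camera adjusted p = 8.81e-05, adjusted p = 0.202 with an estimated correlation). Interferon-stimulated genes had 2 of 20 higher and 5 adjusted over the list alone (camera adjusted p = 0.000185, adjusted p = 0.388 with an estimated correlation). Complement genes (1 of 12 higher, 3 higher and 1 lower adjusted over the list alone), activated microglia genes (0 of 20, 4 adjusted over the list alone) and perivascular and peripheral macrophage markers (0 of 8, 1 adjusted over the list alone) had camera adjusted p of 0.0103, 0.00577 and 0.0103. With an estimated correlation they had adjusted p = 0.202, 0.202 and 0.388. The inflammasome and interleukin-1 genes had 2 of 12 higher, Casp1 and Il33, and 3 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.259). The call for Il33 was lost without CIAS knockout young replicates 2 and 4 (adjusted p = 0.0679 and 0.123). Neurogenesis markers (2 of 20 lower, 4 adjusted over the list alone) and myelin markers (1 of 20 higher, 3 higher and 9 lower adjusted over the list alone) were shifted downward at camera adjusted p of 0.00608 and 0.0273, with adjusted p = 0.169 and 0.632 with an estimated correlation. The comparison called 82 genes, 53 higher and 29 lower, and 133 without wild type old replicate 6, including all 82. It called 42 without CIAS knockout young replicate 2, 34 without CIAS knockout young replicate 4 and 333 with array weights.

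Genes called for age in more than 1 genotype moved in one direction with 32 arrays. Wild type and ASC knockout shared 8 higher and 16 lower genes, against 0.32 and 0.56 for independent lists, and the log2 changes correlated at r = 0.27 across genes. Wild type and CIAS knockout shared 29 higher and 15 lower genes (1.5 and 0.81 for independent lists, r = 0.21), and the knockouts shared 9 and 11 (0.052 and 0.052, r = 0.44). These pairs shared, without wild type old replicate 6, 23 higher and 25 lower, 47 and 24, and 19 and 23 genes, with 3 genes called in opposite directions for wild type and CIAS knockout. These pairs have no arrays in common, and genes are not independent replicates. The fit uses 1 estimate of each gene's spread for all comparisons, so the counts for independent lists can be too low. The age score, a mean over 687 age-responsive genes, rose by 0.35 in wild type, from 0.441 ± 0.0072 (SD, n = 4) to 0.791 ± 0.016 (SD, n = 6), by 0.281 in the ASC knockout and by 0.303 in the CIAS knockout. The rise differed from that of wild type by -0.0689 in the ASC knockout (exact permutation p = 0.000247) and by -0.0468 in the CIAS knockout (exact permutation p = 0.0077). Part of both differences lay in young arrays, with mean scores of 0.471 in ASC and 0.475 in CIAS knockout, above the 0.441 of wild type. Old arrays stood at 0.752 in ASC and 0.778 in CIAS knockout, below 0.791. For CIAS the gap to wild type was wider in young than in old arrays. Without ASC knockout young replicates 1 and 2 the ASC difference was -0.0453 and -0.045 (exact permutation p = 0.00758 and 0.0133). With a covariate for sex-linked transcripts the differences were -0.0488 for ASC and -0.0388 for CIAS (exact permutation p = 0.00303 and 0.0234). The characteristics give 21 months for 5 old ASC samples. Whether a lower age of these samples made the ASC rise smaller was not tested.

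The genes of the score were chosen on the same arrays. In 100 simulations with no genotype difference, such p-values lay under 0.05 in 11 for ASC and in 6 for CIAS. With the genes chosen anew in each relabeling, over 100 labelings with the real one among them, the permutation p was 0.01 for ASC, the smallest they can give, and 0.05 for CIAS, where the call was lost. Without CIAS knockout young replicates 1, 2 and 4 the CIAS difference was -0.0153, -0.0283 and -0.0333, with exact permutation p = 0.3, 0.0853 and 0.0517. Over the genes that fell alone, the ASC difference was -0.0579 with an exact permutation p = 0.0622. The young CASP11 knockout was not part of this test.

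**Figure D2:**
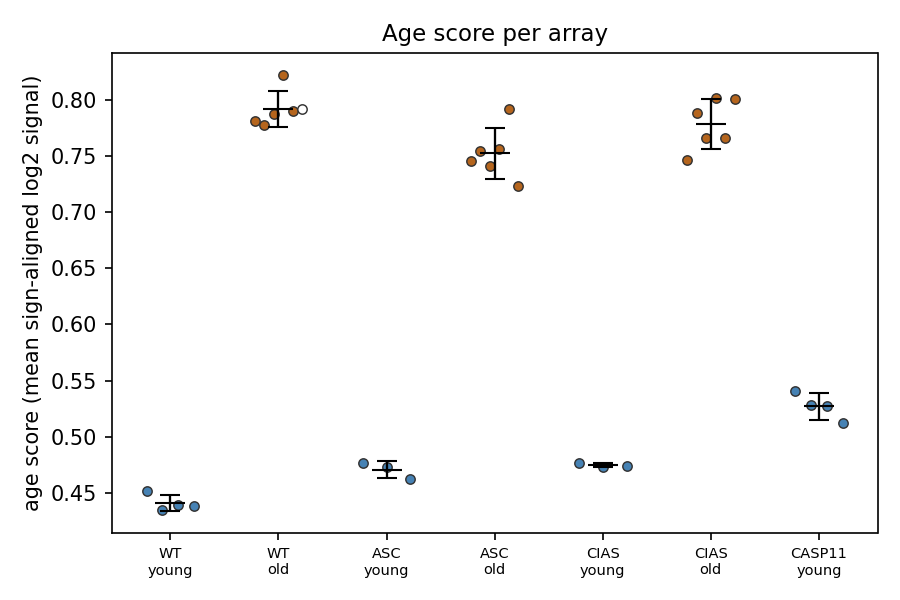
Age score per array (vertical axis, mean sign-aligned log2 signal of 687 genes) in the 7 groups, with young arrays in blue, old arrays in brown and bars for mean ± SD. Old groups lie between 0.752 and 0.791 on average, and young wild type at 0.441, below young ASC (0.471) and young CIAS (0.475) knockout.

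The age effect of some single genes differed between genotypes. Hnrnpl, which encodes a splicing regulator, rose by 1.13 (SE 0.17) in wild type, and its change was -0.47 in the CIAS knockout, a difference of -1.61 (SE 0.25, adjusted p = 0.00412). The young level in wild type, 10.09 ± 0.56 (SD, n = 4), was below those of the young ASC knockout, 11.15 ± 0.058 (SD, n = 3), and the young CIAS knockout, 11.08 ± 0.13 (SD, n = 3). Old wild type stood at 11.23 ± 0.13 (SD, n = 6). Pi4kb, a lipid kinase gene, and Dctn1, a subunit of the dynein cofactor dynactin, rose by 0.97 (SE 0.17) and 0.85 (SE 0.18) in wild type. Their differences in the CIAS knockout were -1.41 (SE 0.25) and -1.52 (SE 0.27, both adjusted p = 0.00764). Nipsnap2 rose by 0.73 in wild type with a difference of -1.27 (SE 0.21, adjusted p = 0.00475). Among genes with a positive difference were the reductase gene Akr1e1 at 0.78 (SE 0.15, adjusted p = 0.0196) and the acetyltransferase subunit gene Naa20 at 0.75 (SE 0.14, adjusted p = 0.0171). Both lost their calls without CIAS knockout young replicate 4 (adjusted p = 0.108 and 0.113).

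For the CIAS knockout 42 genes were called, 12 with a positive and 30 with a negative difference, and for the ASC knockout 2, Hnrnpl at -1.35 and 5730409E04Rik at -0.74, both with adjusted p = 0.0467. Myelin markers had a negative difference in both knockouts (20 measured, 0 called for ASC over all genes or adjusted over the list alone, and for CIAS 0 over all genes and 1 lower adjusted over the list alone). Their medians were -0.45 and -0.39, camera adjusted p = 1.69e-07 and 5.41e-06, and with an estimated correlation adjusted p = 0.771 and adjusted p = 0.791. Wild type old replicate 6 enters both differences and stood at 10.388 for this list, against 9.469 to 9.865 in the other old wild type arrays. Homeostatic microglia markers (18 measured, 0 called by either count) had medians of -0.18 and -0.17 with camera adjusted p = 0.0174 and 0.0253. With an estimated correlation they had adjusted p = 0.771 and adjusted p = 0.791, and by camera 0.0805 and 0.0764 without wild type old replicate 6. Hippocampal subfield markers (16 measured, 0 called by either count) had a positive difference for ASC at camera adjusted p = 0.0132, with adjusted p = 0.771 with an estimated correlation and 0.0805 without that array. Without wild type old replicate 6 the CIAS knockout count was 140, including all 42, and the ASC knockout count 1, and leaving out any single array gave 0 to 4 genes for ASC. That count stayed at 2 only without ASC knockout old replicate 3 or CIAS knockout old replicates 4 or 5. It was 4 without CIAS knockout old replicate 6 and 1 without wild type young replicates 1 or 2, wild type old replicate 6, ASC knockout old replicate 6 or CIAS knockout old replicate 1, and 0 in the 23 other cases. The CIAS count was 18, 27 and 18 without wild type young replicates 1, 3 and 4, and 21 without wild type old replicate 2. It was 82, 22 and 8 without CIAS knockout young replicates 1, 2 and 4, and without replicate 1 the balance turned, with 57 positive and 25 negative differences. It was 83 without ASC knockout old replicate 4 and 89 without CIAS knockout old replicate 5. A fit of only the groups compared gave 17, a covariate for sex-linked transcripts 27 and array weights 265, 132 positive and 133 negative. Of the ASC genes, Hnrnpl had adjusted p = 0.0935 without wild type old replicate 6.

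In old mice, the ASC knockout differed from wild type most in Gdpd3, a lysophospholipase D gene among the 301 tested genes nearest to Pycard. It was 7.34-fold higher (log2 2.88, SE 0.37, adjusted p = 0.000132), at 8.03 ± 0.21 (SD, n = 6) against 5.16 ± 0.16 (SD, n = 6). Young arrays spread widely for this gene, at 6.54 ± 1.3 (SD, n = 3) in ASC knockout and 5.63 ± 1.26 (SD, n = 4) in wild type. Frzb, a secreted Wnt antagonist, was 0.73 higher (SE 0.14) and B4galt4, a galactosyltransferase gene, 0.64 higher (SE 0.12). The potassium channel gene Kcna1 was lower by -1.12 (SE 0.21, adjusted p = 0.00612), the muscle-type cytochrome oxidase gene Cox6a2, also near Pycard, by -1.06 (SE 0.20). The translation regulator gene Cpeb3 was lower by -1.02 (SE 0.205) and the chemokine gene Ccl4 by -0.92 (SE 0.20). Trem2 was lower by -0.41 (SE 0.086, adjusted p = 0.0114) and C1qc by -0.54 (SE 0.11), and the cell cycle inhibitor gene Cdkn1b by -0.61 (SE 0.12). In a fit of these 2 groups alone Gdpd3 and Cox6a2 kept their calls, while Kcna1, Frzb, B4galt4, Cpeb3, Ccl4, Trem2, C1qc and Cdkn1b had adjusted p from 0.0501 to 0.133.

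Of 20 myelin markers in old ASC knockout mice, 3 were lower, 15 adjusted over the list alone (median -0.32, camera adjusted p = 9.67e-09, adjusted p = 0.534 with an estimated correlation). In old wild type, the array of replicate 6 was the highest for this list, at 10.39, against 9.80 ± 0.32 (SD, n = 6) for its group, and without it the list had camera adjusted p = 3.11e-05. Of 18 homeostatic microglia markers 3 were lower, and 4 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.0229, adjusted p = 0.575 with an estimated correlation, 0.0573 without that array). Of 44 named genes called in this comparison, 42 had every knockout array beyond the wild type mean. Interferon-stimulated genes had 0 of 20 lower and 2 adjusted over the list alone (camera adjusted p = 0.00697, adjusted p = 0.697 with an estimated correlation). The comparison called 381 genes, 187 higher and 194 lower, and 432 without wild type old replicate 6, of which 290 were shared. It called 241 and 246 without wild type old replicates 3 and 4, 242, 165 and 111 without ASC knockout old replicates 1, 4 and 5, 29 in a fit of these 2 groups alone and 577 with array weights.

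The old CIAS knockout differed from old wild type in 329 higher and 435 lower genes. Zbtb7a, a zinc finger repressor gene, was lower by -2.51 (SE 0.295, adjusted p = 6.33e-06), at 6.07 ± 1.1 (SD, n = 6) against 8.58 ± 0.26 (SD, n = 6). Kcna1 was lower by -2.10 (SE 0.21, adjusted p = 9.11e-07), the RNA helicase gene Ddx6 by -1.65 (SE 0.28), the ion exchanger gene Slc24a2 by -1.55 (SE 0.24) and the sodium channel gene Scn1a by -1.37 (SE 0.21). Khdrbs3, an RNA-binding protein gene, was 1.22 higher (SE 0.16, adjusted p = 2.17e-05), Frzb 0.80 higher (SE 0.14) and B4galt4 0.72 higher (SE 0.12). The fractalkine receptor gene of microglia, Cx3cr1, was lower by -0.92 (SE 0.13, adjusted p = 6.33e-05), Cdkn1b by -0.91 (SE 0.12), the stress-responsive gene Sesn2 by -0.65 (SE 0.10) and the glutamate receptor gene Gria3 by -0.62 (SE 0.092).

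Myelin markers were lower in the old CIAS knockout for 7 of 20 members and 16 adjusted over the list alone, with Mog, a myelin glycoprotein gene, at -0.72 (SE 0.16), and adjusted p = 0.0705 for Mog in a fit of these 2 groups alone. The list had a median of -0.40, camera adjusted p = 8.18e-10 and adjusted p = 0.534 with an estimated correlation. Wild type old replicate 6, the highest of its group for this list at 10.388, enters this difference too. Of 18 homeostatic microglia markers 5 were lower, 6 adjusted over the list alone (camera adjusted p = 0.00371, adjusted p = 0.559 with an estimated correlation). Meninges and fibroblast markers were shifted upward, with 1 of 15 higher by either count, adjusted over the list alone included (camera adjusted p = 0.0425, adjusted p = 0.749 with an estimated correlation, 0.285 without wild type old replicate 6). Of 64 named genes called, 61 had every knockout array beyond the wild type mean. The comparison called 764 genes, 329 higher and 435 lower, and 786 without wild type old replicate 6, of which 589 were shared. It called 429 without CIAS knockout old replicate 6, and 309 in a fit of these 2 groups alone.

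Old ASC and old CIAS knockouts were compared with the same old wild type arrays, and 99 genes were higher and 146 lower in both. Independent lists of these sizes would share 5.5 and 7.55. Simulations without group differences, with the residuals of all arrays in random order and a shared control group, gave 0 shared genes. With no difference put in few calls can arise, so this 0 says little about the shared genes. The log2 differences correlated at r = 0.81 across genes, which are not independent replicates, against 0.49 on average and up to 0.82 in the simulations, so that r itself lay within their range. Their covariance was 0.03, against 0.0065 on average and up to 0.017. With the controls split between the comparisons, r was 0.41 on average and the shared genes had medians of 5 higher and 32.5 lower. With the 31 arrays 114 genes were higher and 175 lower in both (r = 0.79, with 0.59 on average and up to 0.83 in simulations), and split controls gave medians of 0 and 23.5. The differences in age effect of the knockouts correlated at r = 0.70, with 0.45 on average and up to 0.76 in simulations, a covariance of 0.037 against 0.016 on average and up to 0.041, and 0.28 with split controls.

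In young mice few or no genes separated the ASC and CIAS knockouts from wild type. In the ASC knockout 5730409E04Rik was 0.64 higher (SE 0.11, adjusted p = 0.0174) at 7.04 ± 0.064 (SD, n = 3) against 6.40 ± 0.17 (SD, n = 4). Hnrnpl was 1.05 higher (SE 0.20, adjusted p = 0.0468) and the brain-expressed X-linked gene Chic1 lower by -0.68 (SE 0.13, adjusted p = 0.0468). These were all 3 genes called. With 1 array left out, Hnrnpl lost its call in 25 cases and Chic1 in 23. Leaving out wild type young replicate 4 or ASC knockout young replicates 2 or 4 left 0, with adjusted p for 5730409E04Rik of 0.0694, 0.11 and 0.364. It had adjusted p = 0.0602 without ASC knockout young replicate 1. Leaving out CIAS knockout old replicates 5 or 6 gave 6 and 5 genes. The count was 1 in 19 of the 32 cases, namely without wild type young replicate 3, wild type old replicates 2 to 4, ASC knockout young replicate 1, ASC knockout old replicates 1 to 3, 5 or 6, any young CIAS knockout array, CIAS knockout old replicates 1 or 3, or any CASP11 knockout array. No list was called in this comparison.

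In the young CIAS knockout limma called 0 genes, with 866 at an unadjusted p under 0.05. Without wild type old replicate 6, which enters through the shared spread, the filter and the joint normalization, it called 13, 9 higher and 4 lower. It called 3 without wild type young replicate 2, 4 without wild type old replicate 5, 5 and 1 without ASC knockout old replicates 4 and 6, and 2, 3, 2 and 1 without CIAS knockout old replicates 1, 2, 4 and 5. The deposited normalized values gave 7 genes, as did a strict filter on dim probes and a fit of these 2 groups alone, and array weights gave 52. Immediate early genes, which neurons switch on after activity, were shifted downward (0 of 19 called over all genes or adjusted over the list alone, median -0.24, camera adjusted p = 0.0372), a call that was lost with an estimated correlation (unadjusted p = 0.155). Young ASC and young CIAS knockout differences from wild type correlated at r = 0.53 across genes, against 0.45 in simulations with a shared control group. The covariance was 0.01 against 0.0097, and r was 0.13 with split controls.

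The young CASP11 knockout differed from young wild type most in lower transcripts. Zbtb7a was lower by -3.83 (SE 0.36, adjusted p = 1.95e-07), at 4.77 ± 0.15 (SD, n = 4) against 8.59 ± 0.12 (SD, n = 4). Thsd4, an extracellular matrix gene, was lower by -3.35 (SE 0.48), Kcna1 by -2.21 (SE 0.26), Scn1a by -2.08 (SE 0.26) and the metabolic coactivator gene Ppargc1a by -2.04 (SE 0.26). Cx3cr1 was lower by -1.07 (SE 0.16, adjusted p = 0.000182). The endoplasmic reticulum chaperone gene Hyou1, among the 208 tested genes nearest to Casp4, was 1.099 higher (SE 0.205, adjusted p = 0.00205), the splicing regulator gene Khsrp 0.98 higher (SE 0.16) and the cold-inducible gene Cirbp 0.90 higher (SE 0.12, adjusted p = 2.24e-05). Of 15 circadian clock genes 3 were higher and 3 lower, 5 and 3 adjusted over the list alone, with Dbp at 0.84 (SE 0.15) and Ciart at 0.82 (SE 0.14), both clock output genes, among the higher ones (camera adjusted p of the list 0.148).

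Myelin markers were shifted upward in the young CASP11 knockout (0 of 20 called over all genes or adjusted over the list alone, median 0.29, camera adjusted p = 0.00358, adjusted p = 0.68 with an estimated correlation). MHC genes (0 of 14 called by either count) and interferon-stimulated genes (1 of 20 higher, 2 adjusted over the list alone) were also shifted upward, each with camera adjusted p = 0.022 and adjusted p = 0.68 with an estimated correlation. For MHC genes, replicate 1 stood at 6.94 and the other 3 arrays between 6.03 and 6.21. For interferon-stimulated genes it stood at 7.654 and the others between 6.905 and 7.04, near the 6.938 of young wild type. Cortical layer markers were shifted downward (1 of 11 lower, 1 adjusted over the list alone, camera adjusted p = 0.022, adjusted p = 0.592 with an estimated correlation). The comparison called 299 genes, 92 higher and 207 lower, and 490 without wild type old replicate 6, including all 299. It called 171 and 165 without wild type young replicates 1 and 3, and 157, 150, 142 and 196 without CASP11 knockout replicates 1 to 4. A fit of these 2 groups alone called 618 and array weights 683. With the shared young controls, its differences correlated with those of the young ASC knockout at r = 0.47 (0.46 in simulations, covariance 0.013 against 0.009, 0.17 with split controls). They correlated with those of the young CIAS knockout at r = 0.38 (0.47 in simulations, covariance 0.012 against 0.0096, 0.14 with split controls).

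The genes lower in the young CASP11 knockout overlapped with those lower in old knockouts, comparisons that have no arrays in common. They do use 1 estimate of each gene's spread, so the counts for independent lists can be too low. With the old CIAS knockout 125 lower and 4 higher genes were shared, against 8.1 and 2.7 for independent lists, with 4 called in opposite directions and r = 0.40 across genes. With the old ASC knockout 65 lower and 3 higher were shared, against 3.6 and 1.5, with 4 opposite and r = 0.25. With the 31 arrays the counts were 156 lower, 9 higher and 9 opposite for the old CIAS knockout and 89 lower, 6 higher and 1 opposite for the old ASC knockout.

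**Figure D3:**
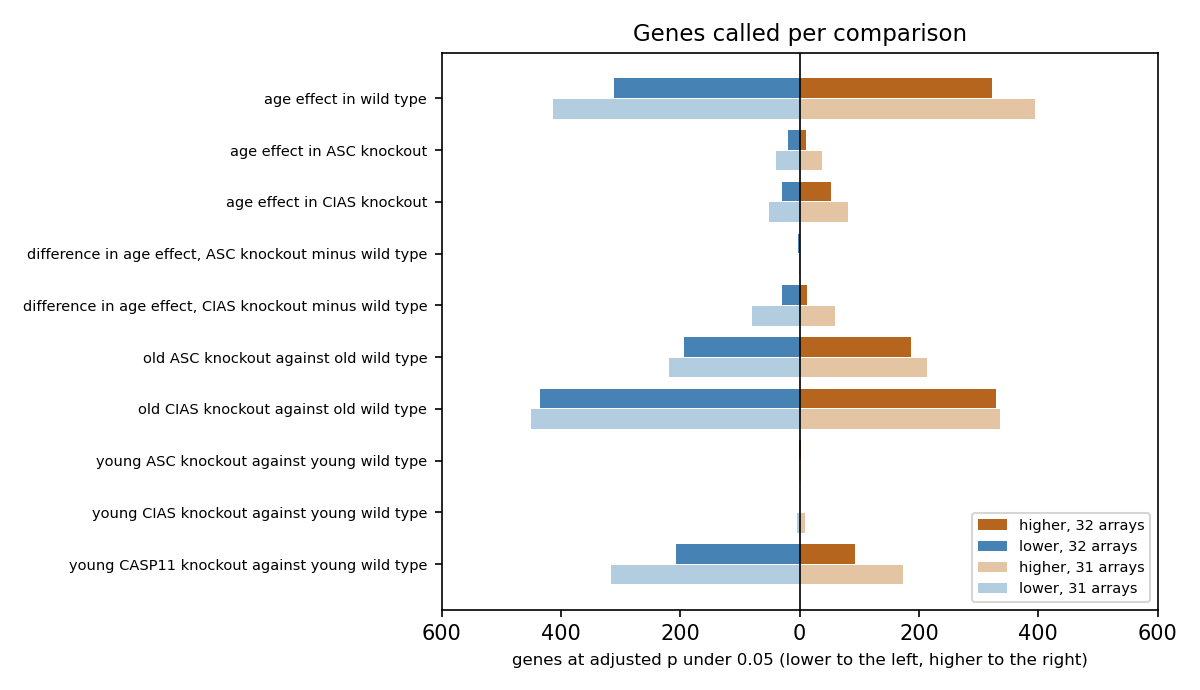
Genes called per comparison at adjusted p under 0.05 (horizontal axis, number of genes), with lower genes in blue to the left and higher genes in brown to the right, for 32 arrays and, in pale bars, 31 arrays without wild type old replicate 6. The longest bars are the 435 lower genes of the old CIAS knockout with 32 arrays and 451 with 31.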

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

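The tests on wild type old replicate 6, on the genes of the old CIAS knockout and on flanking DNA in the old knockouts were chosen after the results were seen. The counts over other splits and the flanking DNA tests in young mice were set before.

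The age effect differed between genotypes in 42 genes for the CIAS knockout and 2 for the ASC knockout, by a test of the difference itself. The same test called 3 gene lists for ASC (myelin, homeostatic microglia and hippocampal subfield markers) and 2 for CIAS (myelin and homeostatic microglia markers), and 0 of these 5 calls held with an estimated correlation. The age score difference was -0.0689 for ASC and -0.0468 for CIAS.

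Some samples lay far from the rest of their group, by the gap to the nearest array over the range of the group. Chance flags about 1 in 20 groups, which is 1.75 of 35 lists and 24.8 of 497 named genes per group. Wild type old replicate 4, which had low Eif2s3y, had the highest age score of its group, 0.822 against 0.777 to 0.792. Its gap was 0.67 of the range. Old wild type had 7 such lists, all in replicate 6, and old CIAS knockout had 7, of which 5 were in replicate 1 (complement, MHC, activated microglia, choroid plexus, and meninges). Young wild type had 3 such lists (myelin and ribosomal protein genes in replicate 1, neurogenesis markers in replicate 4). Old ASC knockout had 1 (striatum and thalamus markers in replicate 3), and young CASP11 knockout had 1 (NF-kB and cytokine genes in replicate 1). Among named genes the numbers were 35 in young wild type, 100 in old wild type, 77 of them in replicate 6, 28 in old ASC knockout, 50 in old CIAS knockout and 30 in young CASP11 knockout.

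Wild type old replicate 6 differed from the mean of the other 5 old wild type arrays by more than 1 log2 unit in 577 of 11178 genes. A dim array is excluded by 13433 detected probes, within the 13172 to 13900 of the others, and a mixture with at least an equal part of hippocampal RNA by 6 hippocampal genes too low for it. The striatum and thalamus list left both striatal tissue and age undecided, with a median difference of 0.431 and a share of 0.17 of the shift in the other old arrays, because its members went both ways. After this was seen the list was divided, and its 6 striatal members were all higher, by 3.16 to 5.01, while the 10 others ranged from -1.7 to 0.706. RNA from the striatum is therefore a candidate source, and age is excluded for these members by a share of 0.009.

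Of 786 genes called in the old CIAS knockout without that array, 507 lost the call when 3 components of the variation within groups were added as covariates (median difference from 0.37 to 0.24) and 279 kept it (from 0.51 to 0.44), but these parts were chosen by the covariates and decide nothing about the cause. In 100 overlapping splits of the old arrays, genes called with one part shifted in the other by a median of 0.53, and by 0.36 with the components as covariates. That shift stayed over 2 SE in all 100 (lowest 2.77 SE), which argues against these 3 components as the whole cause. The components were computed from all arrays of the fit, those in which the shift was measured included. The SE can therefore be too small, and the components are not excluded. The mean shift of the 786 genes was 0.019 in young arrays (SE 0.028, exact permutation p = 0.49) against 0.48 in old ones, a ratio of 0.041. This argues against an effect of the missing gene at any age on the list as a whole. A mean over the list cannot exclude such an effect on some of its genes. An effect of the gene in old age only, a difference in sample handling or RNA quality between the groups and a batch the labels do not name may apply and were not tested.

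DNA of another strain around a targeted gene could change its neighbours. The nearest tested genes, up to 200 on either side, were 208 for Casp4, 301 for Pycard and 400 for Nlrp3. Windows this wide can dilute an excess among the closest genes. Among them, 7 called genes of the CASP11 knockout lay near Casp4 with 5.3 expected by chance (Fisher's exact p = 0.37). For the old ASC knockout 13 lay near Pycard with 9.9 expected (Fisher's exact p = 0.32), and for the old CIAS knockout 18 near Nlrp3 with 26 expected (Fisher's exact p = 0.099). An excess within these windows therefore does not account for these lists as a whole. For single neighbours, such as Gdpd3 and Cox6a2 near Pycard, flanking DNA stays open. Hyou1 and Ddx6 counted as near Casp4 by the order of tested genes only, and their distance from it was not measured. Ddx6 was also lower in the old CIAS knockout, by -1.65, where Casp4 was not the targeted gene. In young ASC and young CIAS knockouts too few genes were called to decide (Fisher's exact p = 1 in both).

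Other splits of the same arrays into groups of the same sizes were counted with the real one included, without adjustment over the comparisons. For age in wild type only the real split called as many (1 of 100, 633 genes against 208 in the highest other). For age in the CIAS knockout 2 of 84 splits, the real one among them, called at least 82 genes. The other, with CIAS knockout old replicates 1, 2 and 6 on one side, called 156. This count therefore excludes neither chance nor a structure of the samples there. Yet 29 higher and 15 lower of the 82 genes were also called for age in wild type, with 0 opposite. Independent lists would share 1.5 and 0.81. These comparisons have no arrays in common but use 1 estimate of each gene's spread, so counts for independent lists can be too low. The spread does not set the direction, and 0 opposite genes argue against chance for the shared genes. By the splits, chance was excluded for the difference in age effect of CIAS (1 of 100, 42 against 24). It was also excluded for old ASC (1 of 100, 381 against 85) and old CIAS knockout (1 of 100, 764 against 301). The same held for the CASP11 knockout (1 of 35, 299 against 3). With 1 array left out the real count ranged from 34 to 133 for age in the CIAS knockout and from 8 to 140 for its difference, and the splits were not counted again there. For the difference in age effect of ASC (1 of 100, 2 against 1) and for young ASC knockout (1 of 35, 3 against 2) no other split reached the real count. That margin of 1 gene was thin, since with 1 array left out the real count was 0 in 23 of 32 cases for the former, and 1 in 19 and 0 in 3 for the latter. This count did not argue against chance for age in the ASC knockout, where 8 of 84 splits called at least the real 31 genes. The highest, 636 genes with ASC knockout young replicate 4 and old replicates 4 and 5 on one side, points to a structure of the samples. Yet 8 higher and 16 lower of the 31 genes were also called for age in wild type, against 0.32 and 0.56 for independent lists. All 31 moved in the same direction in the CIAS knockout. Neither comparison has arrays in common with it, though all use 1 estimate of each gene's spread. The spread does not set the direction, so the common direction argues against chance for these genes. For the young CIAS knockout all 35 splits reached the real count of 0, with 2 in the highest other.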

How the results depend on the processing

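The fits without wild type old replicate 6 combined with covariates, the list tests without that array and the scores with genes chosen anew were chosen after the data had been seen, and the other alternatives before. Counts below are genes called, and the cause was not tested unless stated. With quantile normalization without background correction all 13 results stayed within 1.5 times the count or on their side of the threshold, no called gene or score difference changed sign under any alternative run for it, and no called list did under the 6 run for lists. The balance of higher and lower genes turned in 8 of 47 alternatives for age in wild type and in 11 for old ASC knockout, both near even, in 2 for young ASC knockout and in 1 for the difference in age effect of CIAS (57 positive and 25 negative without CIAS knockout young replicate 1).

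For the difference in age effect of the ASC knockout (2 genes), the count was 0 with the deposited values, no filter on dim probes, the replicate block, trend and robust variance, the sex covariate, only the groups compared and all probes tested separately. For young ASC knockout (3 genes), it was 1 with an offset of 50, the deposited values, no filter, trend and robust variance, and all probes tested separately. For young CIAS knockout (0 genes), it was 7 with the deposited values, a strict filter, and only the groups compared.

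Array weights gave 1044 genes for age in wild type, 109 in ASC and 333 in CIAS knockout, 1 and 265 for the differences in age effect of ASC and CIAS (132 positive and 133 negative for CIAS), 577 for old ASC, 9 for young ASC, 52 for young CIAS and 683 for CASP11 knockout. The sex covariate gave 20 for age in the ASC knockout and 27 for the difference in age effect of CIAS. Only the groups compared gave 204 for age in wild type, 17 for the difference of CIAS, 29 for old ASC, 309 for old CIAS and 618 for CASP11 knockout. All probes tested separately gave 1168 for old CIAS knockout. Requiring at least 1.5-fold, which can only lower a count, gave 110 for age in wild type, 19 in ASC and 39 in CIAS knockout, 45 for old ASC, 162 for old CIAS and 139 for CASP11 knockout.

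With the sex covariate and 31 arrays the counts were 126 for age in the CIAS knockout, 1 and 96 for the differences of ASC and CIAS, and 449 for CASP11 knockout. With the choroid plexus covariate and 31 arrays they were 100 for age in ASC and 190 in CIAS knockout, 1 and 130 for the differences, 1 for young ASC, 13 for young CIAS and 561 for CASP11 knockout. With components of the variation within groups and 31 arrays they were 1047 for age in wild type, 138 in ASC and 249 in CIAS knockout, 0 and 105 for the differences, 122 for old ASC, 385 for old CIAS, 38 for young ASC and 83 for young CIAS knockout.

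The replicate numbers did not pair the arrays, since 0 of 21 pairs of groups had every same-number correlation over 0.1 and the lowest was -0.314. With the number as a block the score differences were -0.0701 for ASC and -0.0474 for CIAS (both permutation p = 0.25, too few splits to pass the threshold), and the ASC difference in age effect had 0 genes. The slide as a block was not run because no slide is given.

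The age score difference of ASC was -0.0579 over the genes that fell (exact permutation p = 0.0622). That of CIAS was -0.0563 over the genes that fell (exact permutation p = 0.0743), -0.0392 over those that rose (p = 0.156) and -0.0496 over 200 genes (p = 0.0526). With genes chosen anew it was -0.0468 (permutation p = 0.05), and -0.0494 with 31 arrays (permutation p = 0.08). Of 54 list calls, 5 held with an estimated correlation, and fry called 34 pairs, 25 of them among the 54.

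Leaving out each array in turn gave 378 to 809 genes for age in wild type, 21 to 77 in ASC and 34 to 133 in CIAS knockout, 0 to 4 for the difference of ASC and 8 to 140 for that of CIAS. It gave 111 to 453 for old ASC, 429 to 826 for old CIAS, 0 to 6 for young ASC, 0 to 13 for young CIAS and 142 to 490 for CASP11 knockout. The score difference ranged from -0.0636 to -0.0153 for CIAS and from -0.0873 to -0.045 for ASC. Of 9344 values of 292 called gene results, 998 lost the call, as did 362 of 3189 under the other alternatives chosen beforehand and 143 of 876 under those added later. Calls were gained by 260 of 38161 values of uncalled gene results with 1 array left out, by 218 of 12931 under the other alternatives chosen beforehand and by 177 of 3579 under those added later. Signal over background limits the targeted genes, since Nlrp3 and Pycard were detected on 0 of 32 arrays.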

Other observations

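No test in this part was planned for these patterns beforehand, and the genes were picked after their values were seen. In old knockout mice C4b, which rose with age in wild type, was lower than in old wild type. It had been picked for being high in the same old wild type arrays. It differed by -0.55 (SE 0.15, adjusted p = 0.0393) in old ASC and by -0.51 (SE 0.15, adjusted p = 0.0381) in old CIAS knockout, with 6 of 6 knockout arrays below the wild type mean in each. Its age effect was not shown to differ from wild type, at -0.49 (SE 0.25, adjusted p = 0.528) for ASC and -0.76 (SE 0.25, adjusted p = 0.154) for CIAS. The complement list was not called in either comparison (4 of 12 lower in each, camera adjusted p = 0.0596 for ASC and 0.233 for CIAS), though it was for ASC without wild type old replicate 6 (camera adjusted p = 0.034). Of its other members, C1qa lost its call in 6 cases with 1 array left out in old ASC and C1qb in 8 in old CIAS knockout. The calls for C4b were narrow. That of old ASC was lost without wild type old replicates 4, 5 and 6 (adjusted p = 0.088, 0.0858 and 0.0573) and ASC knockout old replicates 1 to 4 (0.0705, 0.0639, 0.0559 and 0.0874). That of old CIAS was lost without wild type old replicates 4, 5 and 6 (0.0923, 0.0953 and 0.0635) and CIAS knockout old replicates 1, 3 and 5 (0.0997, 0.0727 and 0.0703).

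Choroid plexus and ependyma markers, genes of the tissue that secretes cerebrospinal fluid, varied within groups. Their mean log2 signal ran from 5.867 to 8.686 in old CIAS knockout and from 6.367 to 9.194 in old ASC knockout. The age score of the 4 young CASP11 knockout arrays lay between 0.512 and 0.541, against 0.435 to 0.452 in the 4 young wild type arrays. That difference was not tested, and the genes of the score were chosen without the CASP11 knockout.

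The lists called changed without wild type old replicate 6, from 54 to 62 of 350 list and comparison pairs, with 45 shared. Immediate early genes were then shifted downward with age in wild type (0 higher and 2 lower of 19, 3 lower adjusted over the list alone, median -0.16, camera adjusted p = 0.0155, adjusted p = 0.53 with an estimated correlation). Heat shock and protein folding genes were too (1 higher and 5 lower of 18, the same adjusted over the list alone, camera adjusted p = 0.0497, adjusted p = 0.516 with an estimated correlation). One array, CIAS knockout old replicate 5, had high Xist, at 7.76, together with high Eif2s3y, at 9.91.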
